A study of Mus musculus with 2 samples.

How the data were processed

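ATAC-seq peak lists from limbs of mouse embryos at 12.5 days were used, from 2 biological replicates that form 1 group, of 88 and 68 pooled embryos. Replicate numbers were taken from the labels. The files are peak lists on mm10, per the notes deposited with them, made from filtered alignments, and neither the peak caller nor its version or settings is given in the sources used here. For each replicate there was a pseudoreplicated list, an IDR-thresholded list and an IDR-ranked list (IDR is the irreproducible discovery rate of ranked peaks). From both replicates together the authors had made a conservative and an optimal IDR-thresholded list, a replicated list, a pooled pseudoreplicated list and 2 IDR-ranked lists. With overlapping rows merged, the replicated list held more intervals (40783) than the pseudoreplicated list of replicate 1 (29793) or replicate 2 (36248). An interval of the replicated list therefore need not be called in each of those lists.

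The signal value of each deposited peak is the enrichment at the summit as the authors' peak caller gave it. The −log10 p and −log10 q of each deposited peak were also taken as the authors gave them, and both grow with sequencing depth. The score of the deposited lists is a display value that was read from the values themselves: in the IDR lists it follows the IDR, with 540 as the lowest score in each thresholded list, and in the others it follows the −log10 p up to a maximum. The peak lists give no read counts or library sizes, so the depth is unknown and no depth-based interval or normalisation between the replicates could be made. Signal values were compared by rank only.

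The lists give a row per summit, so rows that overlap were merged into distinct intervals, each with its highest signal and that summit. Genes and transcription starts were taken from GENCODE M21 (21853 protein-coding genes, 54361 starts of their protein-coding transcripts) and sequence from the GRCm38 assembly, the assembly that mm10 names. Intervals were shared when they overlapped by 1 bp or more, and chance overlap came from 100 random circular shifts. A summit was called promoter within 1000 bp of a start, otherwise exon, intron or intergenic. A gene had a promoter peak when an interval lay within 500 bp of any of its starts. Distal summits lay more than 1000 bp from every start and were assigned to the nearest start within 100000 bp, which need not be the gene they act on.

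The 18 gene lists (312 members, 310 distinct genes, all found), 22 landscapes bounded by named genes and 32 consensus sequences were fixed before the data were examined, as were the comparisons, the rule for named genes and most alternatives. Each list was placed among 10000 random lists, matched member by member in 10 bins of gene length (promoters) or of the distance between the neighbouring genes' starts (distal summits). Landscapes were placed among 1000 random autosomal windows of the same length and class of gene content with at least 90% known sequence. Motif windows reached 100 bp to each side of a distal summit, flanks lay 1000 bp away outside any interval, and up to 20 scrambles of each consensus with the same number of CG pairs served as controls. A motif counted as enriched when its ratio of summit to flank share was above every scramble in both replicates. The HNF1 and REST sites had no match in the flanks of replicate 1, and no scramble of the RFX site gave a ratio, so these 3 could not count as enriched in the main comparison. Lists and landscapes in the top 2.5% or the lowest 2.5% of random ones were named as high or low. These percentiles describe the lists and are not p-values. No p-values were computed, since 2 replicates of 1 group allow no test between groups.

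The genes named were, for each list, the 2 members with the most conservative distal summits and up to 2 without a promoter peak in either replicate, the 10 genes with the most conservative distal summits, the 5 with the best mean promoter rank, the genes nearest to the 3 strongest intervals called in each replicate alone, and all posterior HoxA and HoxD genes. Matches to the mitochondrial genome (at least 100 bp at 90% identity) and to other places in the genome (at least 50% of the interval at 90% identity) were searched with blastn 2.17.0. The functions were tested on simulated data with known answers, and all 22 checks passed. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.

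Alternatives covered the promoter window (500 or 1000 bp), the 5′ end of the gene as its only start, the IDR-thresholded lists, other definitions of a shared interval, a minimum −log10 q of 5, the distance limit (50000 bp), other peak lists, the motif window (50 bp to each side) and flank distance (2000 bp), and each replicate left out. Alternatives added after the data were seen were random lists matched on promoter CpG number, distinct intervals in place of summits, the mean in place of the median, and a single summit per interval. No sample was left out of the main results. Ranked lists were used only to see which rows the thresholded lists lack.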

Results

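Open chromatin was profiled by ATAC-seq, in which a transposase cuts and tags accessible DNA, in limbs of healthy B6NCrl mouse embryos at 12.5 days. There was 1 group with 2 biological replicates, a pool of 88 embryos and a pool of 68 embryos, each of both sexes. The labels do not say whether forelimbs, hindlimbs or both were taken. The deposited files hold called peaks and no reads, so the depth of either library is unknown, and no value here has a depth behind it. With a single group no comparison between conditions was possible. Intervals around shares (Wilson) and around densities (exact Poisson) cover counting error only. All positions are in mm10.

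Promoter peaks set housekeeping genes apart at one end and 8 lists, among them HoxB and hepatic genes, at the other. Of 21853 protein-coding genes, 11888 (54.4%) had an interval within 500 bp of a transcription start in both replicates, 352 in replicate 1 alone, 1168 in replicate 2 alone and 8445 (38.6%) in neither. All 18 housekeeping genes had a promoter peak in both replicates, the 100th percentile among 10000 random lists matched on gene length and the only one of the 18 fixed lists in the top 2.5%. The 8 lists in the lowest 2.5% were HoxB genes (0 of 10), hepatic genes (0 of 18), macrophage genes (0 of 15), germline genes (1 of 15), erythroid genes (3 of 16), osteogenic genes (3 of 14), surface ectoderm and apical ridge genes (4 of 20) and endothelial genes (6 of 18). Hepatic, germline and surface ectoderm genes stayed in the lowest 2.5% under every alternative. Endothelial genes left it without replicate 2 (30.3rd percentile) and with a window of 1000 bp (2.56th), osteogenic genes with that window (3.15th), without replicate 1 (4.765th) and without replicate 2 (2.975th), and HoxB genes with the IDR-thresholded lists (2.725th). Against random lists matched on promoter CpG number, a choice made after the data were seen, osteogenic (2.89th), macrophage (13.2nd) and erythroid genes (56.8th) left the lowest 2.5% and housekeeping genes the top 2.5% (97.2nd). Afp and Ahsg, which encode serum proteins of the fetal liver, Myh6 and Myl2 of the heart, Alas2 of haem synthesis in erythroid cells and C1qa of macrophages had no promoter peak in either replicate. Bglap and Dmp1, genes of mature bone, and Col10a1 of hypertrophic cartilage had none either.

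Promoters did not place the lists of limb genes high in the main comparison, and the places of these lists depended on the comparison made. Limb patterning transcription factors had a promoter peak in both replicates for 14 of 25 genes (46.6th percentile) and limb signalling genes for 15 of 26 (45.6th percentile). Chondrogenic genes stood at 11 of 20 (40.3rd percentile), tendon and connective tissue genes at 9 of 17 (47.1st percentile), myogenic genes at 10 of 20 (39.3rd percentile), Schwann cell and melanoblast genes at 8 of 14 (59.7th percentile), neuronal genes at 8 of 20 (20.4th percentile) and cardiac genes at 5 of 15 (5.87th percentile). Without replicate 1 and without replicate 2, limb patterning transcription factors lay at the 93.4th and 92.6th percentiles, limb signalling genes at the 54.1st and 70.1st, neuronal genes at the 93.1st and 47.3rd, myogenic genes at the 86.8th and 51.6th, tendon genes at the 84.1st and 78.4th and cardiac genes at the 2.045th and 12.4th. With the IDR-thresholded lists limb signalling (0.185th), chondrogenic (0.44th) and myogenic genes (0.17th) lay in the lowest 2.5%, and against lists matched on promoter CpG number so did limb patterning transcription factors (0.11th), limb signalling genes (0.1st) and neuronal genes (0.015th). Shox2 and Tbx5, transcription factors needed for limb growth, had no promoter peak in either replicate, nor did Cyp26b1, which degrades retinoic acid, and Fgf4, a signal of the apical ridge. Single genes differed between the replicates. The promoter of Lmx1b, which specifies dorsal limb, was called in replicate 1 alone, where it ranked 8479 of 29793 intervals by signal, and the promoter of Hand2, a posterior limb factor, in replicate 2 alone, where it ranked 25489 of 36248.

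Within the Hox complexes, most of the posterior HoxA and HoxD genes, which pattern the limb from shoulder to digits, had a promoter peak in both replicates and none of the HoxB genes did. The fixed list of 11 posterior HoxA and HoxD genes includes Hoxd8 and Evx2, and Evx2 is not among the Hox genes counted by cluster below. Of the 11, 7 had a promoter peak in both replicates (63.6%, 96.7th percentile among length-matched lists). They were Hoxa9, Hoxa10, Hoxa13, Hoxd10, Hoxd11, Hoxd12 and Hoxd13. Hoxd13, the most posterior member of its cluster (chromosome 2, 74668310 to 74671599), had the best-ranked promoter peaks of the 11, at rank 7969 in replicate 1 and 10335 in replicate 2. Hoxa11 and Hoxd9 were called in replicate 1 alone, Hoxd8 in replicate 2 alone and Evx2 in neither. The list's place depended on the comparison. It lay at the 99.8th percentile when replicate 1 alone was used, the 98.4th with replicate 2 alone, the 99.05th with a window of 1000 bp, the 78th with the 5′ end of the gene alone, the 41.5th with the IDR-thresholded lists and the 2.9th against lists matched on promoter CpG number, which had a mean of 86.4%, while those matched on gene length had 35.3%. HoxB genes stood at the 0.275th percentile, and at the 0th against lists matched on promoter CpG number. Hoxb4 had a promoter peak in replicate 2 alone.

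**Figure D1:**
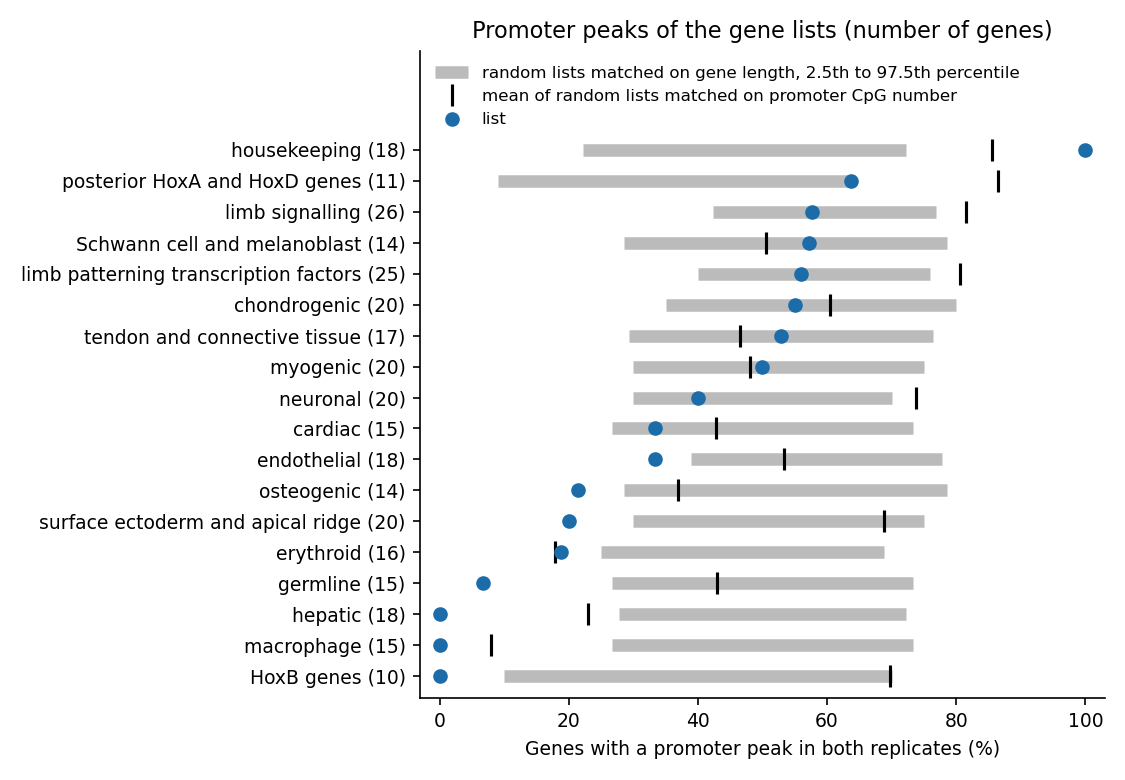
Share of each fixed gene list, in percent, with a promoter peak in both replicates (points), beside the range of 10000 random lists matched on gene length (grey bars, the central 95%) and the mean of random lists matched on promoter CpG number (black ticks). Housekeeping genes lie at 100% and HoxB, hepatic and macrophage genes at 0%.

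Distal peaks, more than 1000 bp from every protein-coding start, placed limb patterning and signalling genes high in the replicated list, but not by their medians in the conservative list. Promoter peaks were scored in the lists of the single replicates and matched on gene length, so their percentiles are not directly comparable with these. In the replicated list the median number of distal summits per gene was 6 for limb patterning transcription factors (99.96th percentile among random lists matched on the distance to neighbouring genes), 5 for limb signalling genes (99.9th), 4 for myogenic genes (99.97th), 3 for surface ectoderm and apical ridge genes (99.9th) and 2 for chondrogenic genes (97.9th). Housekeeping genes, with a median of 1, also lay in the top 2.5% (98.9th), where their random lists had a mean median of 0.0381. Hepatic, germline, erythroid, HoxB and posterior HoxA and HoxD genes had medians of 0. Tendon and connective tissue genes (median 3, 95.1st percentile), neuronal genes (3, 93.5th), osteogenic genes (2, 91.9th), macrophage genes (1, 94.6th), endothelial genes (1.5, 85.5th), cardiac genes (1, 85.2nd) and Schwann cell and melanoblast genes (1, 70.2nd) lay between.

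In their pseudoreplicated lists, the longer ones, the replicates taken alone each placed limb signalling, myogenic, tendon and connective tissue and housekeeping genes in the top 2.5% and differed for some other lists. Limb signalling genes had medians of 2.5 in replicate 1 (99.98th percentile) and 4 in replicate 2 (99.97th), and myogenic genes 3 (100th) and 2.5 (99.7th). Tendon and connective tissue genes had 2 (98.5th) and 3 (98.6th), and housekeeping genes 0.5 (99.6th) and 1 (99.8th). Limb patterning transcription factors had a median of 3 in each, at the 99.9th percentile in replicate 1 and the 96.8th in replicate 2. Surface ectoderm and apical ridge genes had a median of 0 in replicate 1 (44.0th percentile) and 2 in replicate 2 (99.6th), chondrogenic genes 1 (96.9th) and 2.5 (99.94th) and endothelial genes 1 (92.7th) and 2 (98.2nd). In the IDR-thresholded list of either replicate alone every list had a median of 0 and none was in the top 2.5%. The comparison planned as the main one used the conservative list, where 9963 of 38654 summits (25.8%) were distal and only 2823 genes (12.9%) had any distal summit. All 18 lists had a median of 0 there, so that comparison could not separate them.

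**Figure D2:**
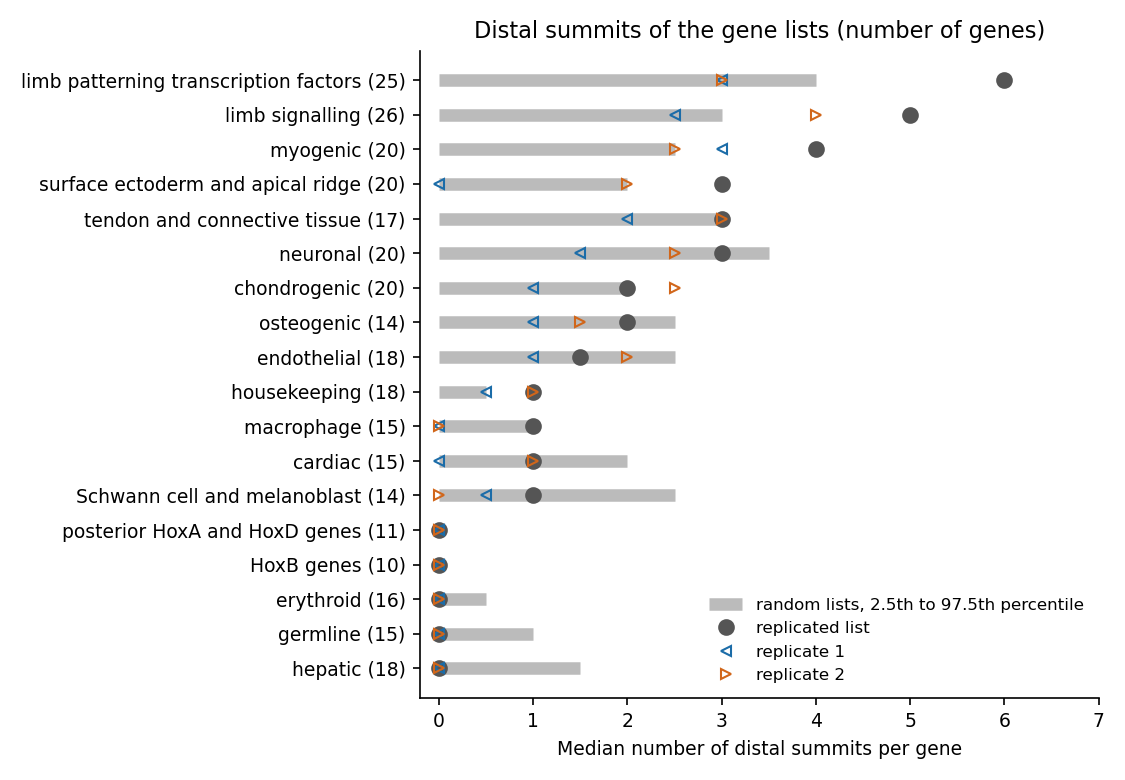
Median number of distal summits per gene for each fixed list in the replicated list (filled points) and in replicate 1 and replicate 2 alone (open triangles). Grey bars span the central 95% of the medians of random lists for the replicated list alone. Limb patterning transcription factors, at 6, and limb signalling genes, at 5, lie farthest to the right.

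Among single genes, Fgfr1, a receptor for fibroblast growth factors (chromosome 8, 25513654 to 25575718), had 17 conservative distal summits, 8 in the IDR-thresholded list of replicate 1 and 11 in that of replicate 2. An interval can hold several summits, and by distinct conservative intervals, each placed by its strongest summit, Fgfr1 had 5. Further summit counts are followed by those in the same lists of replicate 1 and replicate 2. Mef2c of the myogenic list had 10 (2 and 7). Col2a1 and Acan, which encode the main collagen and proteoglycan of cartilage, had 6 (3 and 2) and 5 (2 and 4). Hand2 had 6 (2 and 4) and Lmx1b had 6 (0 and 2). By distinct intervals Mef2c and Hand2 had 3 each, Col2a1 had 4, and Acan and Lmx1b had 2 each. Tbx5, without a promoter peak, had 0 conservative but 12 replicated distal summits. In the pseudoreplicated lists Tbx5 had only 3 in replicate 1 and 1 in replicate 2. Wnt7a of dorsal ectoderm, in the limb signalling list, had 4 conservative distal summits (0 and 0). Such counts were not particular to limb genes. Col1a1 had 5 (2 and 3). Grhl3 of surface ectoderm (0 and 0) and Mkx of tendon (2 and 4) had 4 each. So did the vascular cadherin gene Cdh5 (3 and 2), Fli1 of the endothelial list (3 and 4) and Laptm5 of the macrophage list (4 and 3). The neuronal genes Snap25 (1 and 2) and Tbr1 (0 and 0) also had 4 each. Tfap2a of surface ectoderm (2 and 3), Klf1 of erythroid cells (0 and 1), Tnni3 of the cardiac list (2 and 1) and the housekeeping genes Eef1a1 (2 and 3) and Ubc (1 and 2) had 3 each. By distinct intervals Col1a1, Cdh5, Snap25 and Tbr1 had 2 each, and the other genes from Wnt7a to Ubc had 1 each. Over all genes the most conservative distal summits were assigned to Eapp with 23 (16 and 12), BC107364 with 18 (15 and 10), Fgfr1, Gse1 (7 and 9) and Maml3 (11 and 17) with 17 each, 4930558K02Rik (10 and 9), Dnmt3a (3 and 14), Gm21119 (9 and 6) and Tenm4 (3 and 12) with 16 each and Lrig3 with 15 (1 and 1), so the order differed in single replicates. By distinct intervals these genes had from 4 (Dnmt3a) to 7 (Lrig3, Tenm4 and 4930558K02Rik), and Eapp had 6. The promoters with the best mean rank by signal were those of Arrdc4, Wdr17, Kifap3, Tmem218 and 2610008E11Rik, at ranks 15 to 36 in replicate 1 and 12 to 26 in replicate 2.

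The gene deserts beside HoxD and Sox9, which hold long-range limb and cartilage enhancers, carried more intervals than most windows of like length and gene content in the replicated list. The telomeric desert of HoxD (chromosome 2, 74878432 to 75659260) held 4 conservative intervals, 5.12 per Mb (95% Poisson interval 1.40 to 13.1), the 99.4th percentile among 1000 random windows and the only one of 15 limb landscapes in the top 2.5%. In the replicated list it held 22 intervals, 28.2 per Mb against a random median of 2.56 (99.9th percentile), with 12 in replicate 1 and 17 in replicate 2. The HoxD cluster itself held 20 replicated intervals (178.3 per Mb, 100th percentile), against 7 in replicate 1 and 13 in replicate 2. The HoxA cluster held 17 (97.8th), against 12 and 16, and the desert downstream of Sox9 14 (98.8th), against 17 and 10. The desert upstream of Sox9 held 14 (97.2nd percentile), against 9 and 8. The interval from Pitx1, a hindlimb factor, to H2afy also held 14 (97.2nd), against 7 and 7. The interval of Fgf8 and Fbxw4 held 10 (96.6th), against 5 and 3. Apart from the telomeric desert these places were lower in the conservative list, where the HoxD cluster held 2 intervals (33.3rd percentile), below the random median, the HoxA cluster 5 (72.4th), the Sox9 downstream desert 2 (94.05th), the Sox9 upstream desert 3 (96.75th), Pitx1 to H2afy 3 (89.9th) and Fgf8 and Fbxw4 0 (15.15th). Without replicate 1 and without replicate 2, in the IDR-thresholded lists, they lay at the 27.3rd and 29th percentiles (HoxD cluster), the 30.75th and 45.6th (HoxA cluster), the 96.1st and 44.4th (Sox9 downstream), the 81st and 92.75th (Sox9 upstream), the 15.6th and 62.85th (Pitx1) and the 18th and 67th (Fgf8).

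Other limb landscapes did not stand out in the replicated list. The centromeric HoxD desert held 12 intervals (82.1st percentile), Grem1 and Fmn1 11 (87.0th), Tbx5 to Rbm19 6 (94.2nd), the Gli3 gene 7 (77.2nd), the Meis2 gene 4 (60.6th), Ihh and Nhej1 4 (63.7th) and the HoxA digit landscape 2 (73.9th). The interval from Shh through Lmbr1, which holds the long-range limb enhancer of Shh, held 3 (3.05th percentile). None of 7 landscapes of other tissues reached the top 2.5% in either list, the highest being the Neurod6 interval at the 90th percentile in the conservative list. The albumin (13.6th percentile), casein (5.6th) and beta-globin clusters (9.7th) and the cardiac myosin genes Myh6 and Myh7 (9.7th) held 0 replicated intervals. None of these places was in the lowest 2.5%. Apart from the casein cluster (266 kb) these windows were short, at 48.0, 40.7 and 52.7 kb. Counts of conservative intervals were small, and in the IDR-thresholded list of either replicate alone the telomeric HoxD desert held 1 interval and fell below the top 2.5%, at the 94.5th percentile in replicate 1 and the 87.4th in replicate 2.

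**Figure D3:**
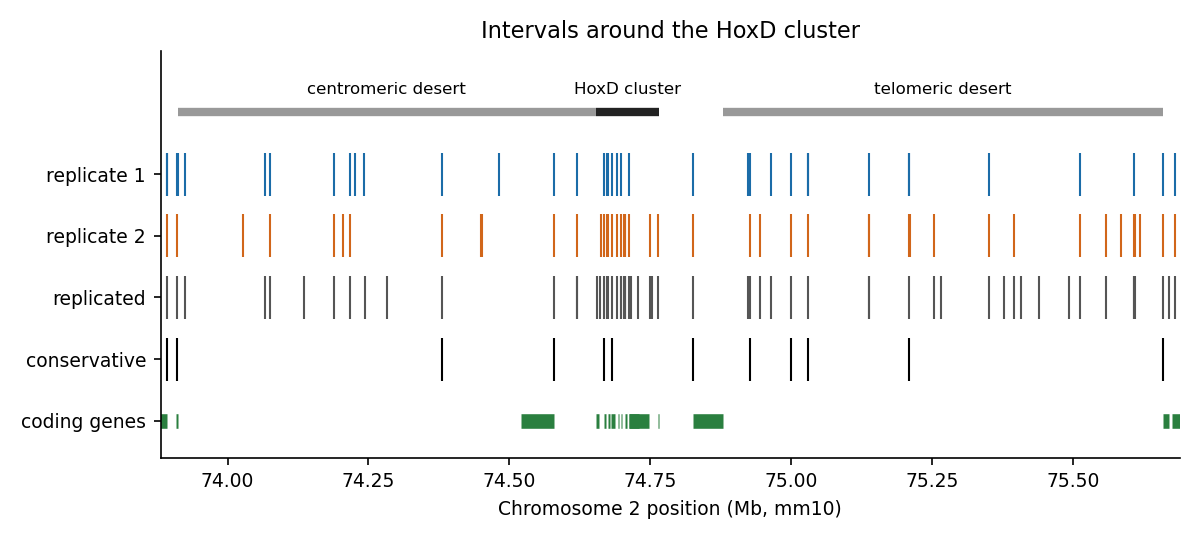
Map of the HoxD region on chromosome 2 in mm10, with the midpoint of each interval of replicate 1, replicate 2, the replicated list and the conservative list as a tick, and protein-coding genes as green blocks. The telomeric desert, free of coding gene starts, holds 12 intervals in replicate 1, 17 in replicate 2, 22 in the replicated list and 4 in the conservative list.

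Of 32 consensus sequences tested at distal summits, 3 of which (HNF1, REST and RFX) could not be judged, 8 were more frequent relative to flanking windows than every scrambled version of themselves in both replicates, and 5 of these were also more frequent at summits than in the flanks. The CAGCTG E-box, bound by MYOD and other bHLH factors, was in 20.3% of summit windows of replicate 1 and 20.8% of replicate 2, against 9.38% and 9.20% of flanks (ratios 2.17 and 2.26). The TEAD site had ratios of 1.67 and 1.76, the SP/KLF site 5.36 and 4.71, and the CTCF site 3.91 and 4.78. The palindromic NFI site had the highest ratios, 7.09 and 15.8, but occurred in only 0.118% and 0.125% of summit windows. Its share of flanks was 0.0167% and 0.00792%, so these ratios rest on few matches. The CTCF site passed its highest scramble in replicate 1 narrowly (3.91 against 3.90) and did not in the conservative list (3.64 against 7.38).

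The other 3, the posterior HOX site (ratios 0.783 and 0.946), the homeobox core TAATTA (0.630 and 0.771) and the MEF2 site (0.895 and 0.977), were less frequent at summits than in the flanks, though less depleted than scrambles of the same AT-rich composition. GATA, HNF4, PITX, RUNX and SOX sites did not pass in either replicate, and the AP-1, GLI and NFY sites passed in replicate 1 alone. With windows of 50 bp to each side the homeobox core no longer passed and the AP-1 site did. At a flank distance of 2000 bp the CTCF site no longer passed and the GLI, NRF1 and RFX sites did. With the IDR-thresholded list of either replicate alone the CTCF site did not pass and the NFY and NRF1 sites did. The NFI site gave no ratio there, so it could not be judged.

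Promoters took a much larger share of summits than of the genome. Within 1000 bp of a protein-coding start lay 52.6% ± 3.66 (SD, n = 2) of the summits of the replicates and 74.2% of the conservative summits, against 2.44% of the sequenced genome. Introns held 21.8% ± 2.10, intergenic sequence 21.5% ± 1.44 and exons 4.21% ± 0.129 (SD, n = 2). The conservative list was poorer in introns (10.8%), intergenic sequence (11.98%) and exons (2.98%). These are shares of summits, and an interval can hold several. Counted as distinct intervals, each placed by its strongest summit, most in each replicate were distal. These were 16783 of 29793 in replicate 1 and 22256 of 36248 in replicate 2, against 4368 of 14130 in the conservative list.

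The X chromosome, present in the pools from both sexes, was sparse in distal intervals. It carried 1.57 per Mb in replicate 1 and 2.29 in replicate 2, against autosomal medians of 6.83 and 8.95, a ratio of 0.243 ± 0.0180 (SD, n = 2). The autosome with the fewest had 5.85 per Mb in replicate 1 and 7.59 in replicate 2. With all intervals the ratio was 0.357, and with the distal intervals of the IDR-thresholded lists 0.444 ± 0.0775 (SD, n = 2).

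The replicates shared nearly all of their strong intervals and few of their weak ones. Replicate 1 had 29793 distinct intervals (50838 deposited summits, median width 463 bp, 16.3 Mb) and replicate 2 had 36248 (68761 summits, 565 bp, 23.2 Mb). Of the replicate 1 intervals, 70.7% (70.2 to 71.2) overlapped one of replicate 2, against 1.65% after random shifts along the chromosomes, and 56.7% (56.2 to 57.2) of the replicate 2 intervals overlapped one of replicate 1, against 1.36%. Among the strongest 10% by signal 99.9% of replicate 1 and 99.5% of replicate 2 intervals were shared, and among the weakest 10% 33.9% and 21.9%. Across the 21074 shared intervals of replicate 1, which are not independent replicates, signal values ranked alike with a Spearman rho of 0.759. The lists made by the authors from both replicates held 14130 (conservative), 15240 (optimal), 40783 (replicated) and 44239 (pooled) distinct intervals.

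**Figure D4:**
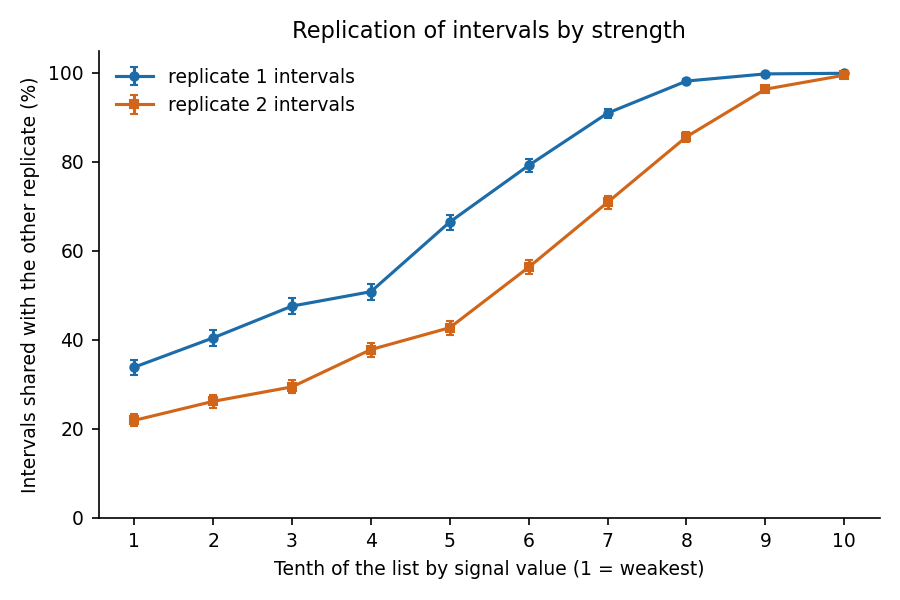
Share of intervals, in percent with Wilson 95% intervals, that overlap an interval of the other replicate, for each of 10 equal parts of the list of replicate 1 (circles) and replicate 2 (squares) from the weakest signal to the strongest. The share rises from 33.9% to 99.9% in replicate 1 and from 21.9% to 99.5% in replicate 2.

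The intervals called in 1 replicate alone mostly lay low in their own list, with median signal percentiles of 23.1 in replicate 1 and 29.1 in replicate 2, and the 3 strongest of each are given here. In replicate 2 the strongest lay on chromosome 13 (15394956 to 15395702), 67905 bp from the start of Gli3, a transcription factor of digit patterning, with a signal of 10.99 at rank 1927 of 36248. The next lay at the promoters of Tll2 (signal 10.96) and Mapk10 (signal 10.5). In replicate 1 the strongest lay on chromosome 16 (35981610 to 35981884), 1581 bp from the start of Kpna1, with a signal of 12.2 at rank 373 of 29793. The others, with signals of 8.76 and 7.43, were nearest to Atrnl1 and Olfr161, at 315573 and 476363 bp. All 6 were also in the pooled list.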

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

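The tests below were chosen after the patterns were seen, and each test's expected outcomes were written before it was run. For 3 of them the rule that turned the value into a verdict was changed to undecided after the value was seen: the promoter test and the test of X copies had counted against their explanations, and the test of depth or enrichment had counted for it. No biological explanation of a difference between groups was tested, since the design has 1 group. The mixture of cell types and the number of X copies were weighed as properties of the pools.

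Rows of the IDR-ranked lists that no comparison used passed the score of the thresholded lists and are missing from them. They number 196 of 22470 rows past that score in replicate 1, 164 of 29799 in replicate 2, 211 of 38865 for the conservative list and 231 of 41355 for the optimal list. For the conservative list 57 of them lie on unplaced scaffolds and 154 in 62 intervals on chromosomes, of which 32 have at least 1 near-identical place elsewhere in the genome. The strongest (chromosome 1, 24611586 to 24616168, −log10 p 6709, above the 6009 of the strongest interval kept) matches the mitochondrial genome over 4583 bp at 99.956% identity. Why these rows were left out is not given in the sources used here.

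The 20 strongest conservative intervals by −log10 p include sequence that the nucleus shares with mitochondria. A match to the mitochondrial genome was found in 6 of the 20, all among the strongest 7, with lengths of 129 to 1633 bp and identities of 97.4% to 100%, against 0 of 500 other conservative intervals drawn at random, so reads from mitochondrial DNA placed on nuclear copies are a candidate source of these intervals. Near-identical nuclear copies were found for 3 of the 20, against 0.48 expected, and all 3 also match mitochondrial DNA, which leaves this explanation undecided. Promoters were 10 of the 20, which met both bounds set for this test because 14.02 were expected from their share among all conservative intervals, so it decided nothing. None of the strongest 9 was a promoter, and 10 of the following 11 were.

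Replicate 2 had more intervals than replicate 1 (36248 against 29793). The 15701 intervals called in replicate 2 alone had a median signal percentile of 29.1 in their own list, against 69.8 for shared ones. The 8719 called in replicate 1 alone lay lower still in theirs (23.1), although that list is the shorter one, so a low place of unshared intervals does not bear on why replicate 2 has more. A difference in depth or enrichment between the libraries stays open. A different mixture of cell types stays open too: of 11 lists with 10 or more distal intervals called in replicate 2 alone, the highest ratio to the shared rate was 1.80, for cardiac genes, from 13 intervals, and in intervals of replicate 1 alone that list's ratio was 1.94, from 8.

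Distal intervals were sparser on the X chromosome than on the autosomes. Against autosomal windows of 1 Mb matched on gene starts, GC and repeat content, the X held 0.460 ± 0.0273 (SD, n = 2) of the expected number, compared with 0.248 without matching. In replicate 1 and replicate 2 it was 0.441 and 0.480, which met the bound written against sequence and gene content as the explanation. The ratio was higher with matching than without, so these features as matched go with part of the deficit. As matched, they left the rest of the deficit. The median repeat content was 45.8% for the X and 31.7% for the autosomes. How closely the matched windows came to the X is not given here, so a remaining difference in these features could not be excluded. Fewer X copies in the pool could not be decided: 41.5% of 948 X-linked coding genes had a promoter peak in both replicates, against 41.0% (38.9 to 43.2) in autosomal sets matched on promoter CpG number. This met the bound written against the explanation, but only within the spread of the matched sets, and strong promoters could be called at a lower copy number too.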

How the results depend on the processing

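Counting deposited rows in place of distinct intervals gives 50838 and 68761 for the replicates and 38654 for the conservative list. The share of replicate 1 in replicate 2, and of replicate 2 in replicate 1, was 56.1% and 46.1% at 50% reciprocal overlap, 68.9% and 53.6% by summits, 87.3% and 72.4% with IDR-thresholded lists, 89.9% and 59.8% at a −log10 q of 5 or more, and 66.3% and 63.8% for equal numbers of intervals, always higher for replicate 1. Rank agreement stayed at 0.747 to 0.795. Promoter, intron, intergenic and exon shares were 46.0%, 25.1%, 23.1% and 5.82% with a window of 500 bp, 80.9%, 7.74%, 9.05% and 2.33% with IDR-thresholded lists, and 45.8%, 25.9% and 6.93% for promoter, intron and exon with the 5′ end alone. The X ratio was 0.357 with all intervals and 0.444 with IDR-thresholded lists, below 1 in each. Lists high for promoter peaks numbered 1 in the main comparison, 2 with a window of 1000 bp (the posterior HoxA and HoxD genes joined), 2 with either replicate left out and 0 with random lists matched on promoter CpG number, a choice made after seeing the data. Lists high for distal summits numbered 0. They also numbered 0 with either replicate left out, where the IDR-thresholded lists gave every list a median of 0. In the pseudoreplicated lists they numbered 5 in replicate 1 and 7 in replicate 2. With the optimal list 3 were high (limb patterning, tendon and neuronal), and with the replicated list 6. With the mean in place of the median, also chosen after seeing the data, 1 was high (limb signalling). Limb landscapes in the top 2.5% numbered 1, and 4 with the replicated list and 2 with windows of the same chromosome. With either replicate left out, in the IDR-thresholded lists, they numbered 0. Motifs above every scramble numbered 8 to 10 under every alternative, of which 6 to 8 were those of the main comparison. Of the 8 in the main comparison, 3 were less frequent at summits than in the flanks. Depth, which the files do not give, can limit which weak intervals are called, and its part here could not be measured. No list or landscape went from the top 2.5% to the lowest 2.5% or back, but with promoter CpG matching the posterior HoxA and HoxD genes went from the 96.7th percentile, above the mean of random lists, to the 2.9th, below it. Apart from the values above the cause of a change was not tested.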

Other observations

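The following were chosen after the data were seen. Calls at the promoters of the 39 Hox genes were counted by cluster, without a test of the difference. Promoter peaks in both replicates were found for 5 of 9 HoxD genes, 5 of 11 HoxA genes, 3 of 9 HoxC genes (Hoxc5, Hoxc10 and Hoxc13) and 0 of 10 HoxB genes, of which only Hoxb4 had one in replicate 2 alone. In HoxA the calls fell at Hoxa1, Hoxa7, Hoxa9, Hoxa10 and Hoxa13, and Hoxa2, Hoxa3, Hoxa5 and Hoxa6 had none in either replicate. In HoxD only Hoxd4 had none in either. The median number of promoter CpG followed the same order as the share called, 70 in HoxD, 69 in HoxA, 52 in HoxC and 48 in HoxB. Against random lists matched on promoter CpG number, HoxB genes lay at the 0th percentile (0% against a mean of 69.8%). This argues against promoter CpG number alone as the reason for the lack of HoxB calls. Otherwise the clusters were not compared apart from CpG number. The Hox promoter peaks are calls at a threshold, and the promoters called in both replicates ranked from 7969 (Hoxd13) to 28255 (Hoxa10) of 29793 intervals in replicate 1.

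Some distal intervals lay at genes that are not protein-coding. Of 4368 distal conservative intervals, 378 (8.65%, Wilson interval 7.86 to 9.52) overlapped 1000 bp around the start of a long noncoding RNA gene, against 1.06% after random shifts, and 64 (1.47%, 1.15 to 1.87) lay within 100 bp of a transfer RNA gene, against 0.0181%. The transfer RNA genes reached were 81 of 403 in the conservative list, 96 in replicate 1 and 110 in replicate 2. The counts of distal summits per gene include such intervals.

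Against random lists matched on promoter CpG number in place of gene length, 8 lists lay in the lowest 2.5% and none in the top 2.5%. Limb patterning transcription factors fell to the 0.11th percentile (56.0% against a mean of 80.6%), limb signalling genes to the 0.1st, neuronal genes to the 0.015th and posterior HoxA and HoxD genes to the 2.9th, while erythroid genes rose to the 56.8th and macrophage genes to the 13.2nd. A test prepared before this value was seen asked whether CpG-rich promoters lay behind a high place of limb patterning transcription factors, but their list stood at the 46.6th percentile, so there was nothing to explain.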
